A study of Mus musculus with 2 samples.

How the data were processed

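MicroRNA-seq was made from pooled forebrain of E11.5 mouse embryos, as 2 libraries that the labels number as biological replicates 1 and 2 of 1 group. The labels give them separate tissue samples of 109 and 88 embryos and the same donor entry. Per the labels and the text files deposited with the counts, reads were aligned to the mm10 build and counted per miRNA gene of the GENCODE M4 annotation. The aligner and counter are not given in the sources used here. The first 4 rows of each file (unmapped, multimapping, no feature, ambiguous) have the layout of the gene count table that STAR writes, and they were kept out of library totals and tests. Each deposited file holds raw counts in 3 columns, for both strands together, for the strand of the gene and for the opposite strand, all whole numbers. The strand columns added up to the unstranded count for every gene.

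The column rule, the 15 lists of miRNA genes and the rule for named genes were all set before the data were examined. The column rule took the strand column with the larger total in both libraries, which was the sense column, with 96.4% and 96.8% of the gene counts. Reads mapping to several places stand in a row of their own, 1165381 in replicate 1 and 1001079 in replicate 2, or 40.4% ± 1.82 (SD, n = 2) of the mapped reads, and are not in the gene counts. Levels of genes with identical or nearly identical copies can therefore be too low by an unknown amount. Levels are CPM over the sense counts of all miRNA genes, 1281201 and 1297647 counts, at which 3 counts are 2.34 and 2.31 CPM. A share of a single library has a 95% Wilson interval.

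Of 1973 gene identifiers, 1894 were found in GENCODE M21 on GRCm38, the assembly that mm10 names, which gave symbols, positions and host genes. The other 79 held 1 and 2 counts. Annotation M4 was not used here. The hairpins of M21 were compared with each other for shared stretches of 20 bases, among miRNA genes only, since no genome sequence was used. The 15 lists have 212 members, of which 196 had a row. Symbols that have changed were matched through RefSeq synonyms (Mir486a, Mir146a, Mir301a and Mir292a appear as Mir486, Mir146, Mir301 and Mir292, and Mir142a and Mir486b as Mir142 and Mir3107, which have no row).

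The text names the 20 genes with the highest mean CPM, up to 4 members of each list by mean CPM and, of the genes called different between the libraries with a mean of 50 counts or more, the 5 furthest in each direction. Genes named outside this rule, after their values were seen, were Mir9-2, Mir9-3, Mirlet7b, Mirlet7c-2, Mirlet7f-2, Mir19a, Mir19b-1, Mir92-1, Mir294, Mir1a-1, Mir133a-1, Mir133a-2, Mir133b, Mir122, Mir211, Mir7666, Gm23935, Gm24572, Mir124a-1, Mir124a-2, Mir124a-3 (as a sum), Mir142, Mirlet7e and Mirlet7f-1 (which have no row), Mir376b, Mir758, Mir19b-2 and Mir92-2 (as copies only), and those of the closing part. Of the genes named by the rule, Mir487b, Mir302a, Mir302b, Mir411, Mir486, Mir146 and Mir194-2 share a stretch of 20 bases with another hairpin.

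No comparison between conditions exists in the series, and none was made. For each gene with 10 counts or more in total, a two-sided exact binomial test compared the 2 libraries against their totals, with Benjamini-Hochberg adjustment over the 398 genes, a threshold of 0.05 and a 2-fold minimum, and 0.5 counts added for the log2 ratio. Intervals of log2 ratios are exact Clopper-Pearson intervals and cover counting error only. The common dispersion was estimated in edgeR 4.0.16 with TMM factors in an intercept-only design, and is given as the biological coefficient of variation. List medians of the level were placed among 10000 random lists of the same size, drawn from the genes with a count in either library or on a list. Medians of the log2 ratio were placed among 10000 lists matched on level in 10 bins. Scripts ran in R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

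The binomial test was tested on simulated counts for the genes and library sizes of replicates 1 and 2, with 200 genes changed and counting error alone. Of 50 genes changed at each of 2-fold, 3-fold, 4-fold and 6-fold, 25, 21, 32 and 37 had enough counts to be tested. The test recovered 56.0% of the tested genes changed 2-fold, 95.2% of those changed 3-fold, 87.5% at 4-fold and 91.9% at 6-fold. The 2-fold set stood at the threshold itself. Recovery with spread between libraries was not simulated. Without changes, 20 draws with counting error alone gave at most 0 calls, and 20 draws with the spread edgeR estimated gave at most 5. In a simulation of 398 unchanged genes, edgeR returned coefficients of variation of 0.0438, 0.0877 and 0.206 for true values of 0.05, 0.1 and 0.2, whereas the median gene-wise dispersion of DESeq2 1.42.0 returned its floor for 0.05 and 0.1.

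Alternatives covered the detection limit, filters on low counts, TMM and DESeq2 scaling, the edgeR exact test, the pseudocount, the unstranded column, removal of dominant genes and each replicate alone. After the data were seen, the opposite-strand counts of rows overlapping list members without a row were added as a further alternative, and the counts of higher and lower genes per list were worked out again with TMM and DESeq2 scaling. The alignments and signal tracks that the deposited text files list were not used here.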

Results

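Short RNA was sequenced from the forebrain of mouse embryos of strain B6NCrl at embryonic day 11.5 (E11.5), when the forebrain consists largely of dividing neural progenitors. The assay, microRNA-seq, reads RNA of the length of mature microRNAs (miRNAs), the small RNAs that repress messenger RNAs and are cut from hairpins encoded by miRNA genes. The series held 1 group with 2 biological replicates and no control or treated group, so its comparisons are between miRNA genes, between lists of miRNA genes and between the replicate libraries. Tissue of 109 embryos was pooled for replicate 1 and of 88 embryos for replicate 2, with both sexes in each pool. Replicate 1 held 3955893 reads and 1281201 counts on the sense strand of miRNA genes, and replicate 2 held 3428269 reads and 1297647 such counts. These counts were 35.1% ± 3.86 of the reads (SD, n = 2, as for every value given with ± below), and 29.3% ± 0.183 of the reads mapped to several places, 27.3% ± 2.82 were unmapped and 6.98% ± 0.896 mapped outside miRNA genes. Levels are given as CPM, the counts of a gene scaled to the sense counts of all miRNA genes in its library, and genes are named with positions in the mouse build mm10.

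Mir335, which lies in an intron of the imprinted gene Mest, had the most counts of the miRNA genes in the E11.5 forebrain libraries, among reads that map to a single place, at 92176 ± 6809.9 CPM or 9.22% of the counts. Mir17, a hairpin of the Mir17hg transcript that carries the miR-17-92 cluster known from dividing progenitors, followed at 65099 ± 8463 CPM, and Mir99a at 57079 ± 2589 CPM. These genes held the first 3 ranks in the same order in both libraries. Mir130a had 39525 ± 1495 CPM, Mir99b 33339 ± 3117 CPM and Mir126a, known from blood vessel endothelium, 32462 ± 3025 CPM. Mir335 (ENSMUSG00000065501) stands on chromosome 6 from 30741299 to 30741396, Mir17 (ENSMUSG00000065508) in an exon of Mir17hg on chromosome 14 from 115043671 to 115043754, and Mir99a (ENSMUSG00000065530) in an intron of Mir99ahg on chromosome 16 from 77598936 to 77599000. Mir126a (ENSMUSG00000065540) overlaps an exon of Egfl7 on chromosome 2 from 26591357 to 26591429. Mir20a at 27745 ± 3763 CPM, Mir30e at 25025 ± 1327 CPM, Mir93 at 19797.5 ± 634 CPM and Mirlet7g at 18769.6 ± 1131 CPM completed the 10 most abundant genes. Mir106b, Mir322, Mir92b, Mir26b, Mir18, Mir149, Mir100, Mir744, Mir487b and Mir181d came next, from 18344 ± 929 CPM for Mir106b to 11394 ± 758 CPM for Mir181d.

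**Figure D1:**
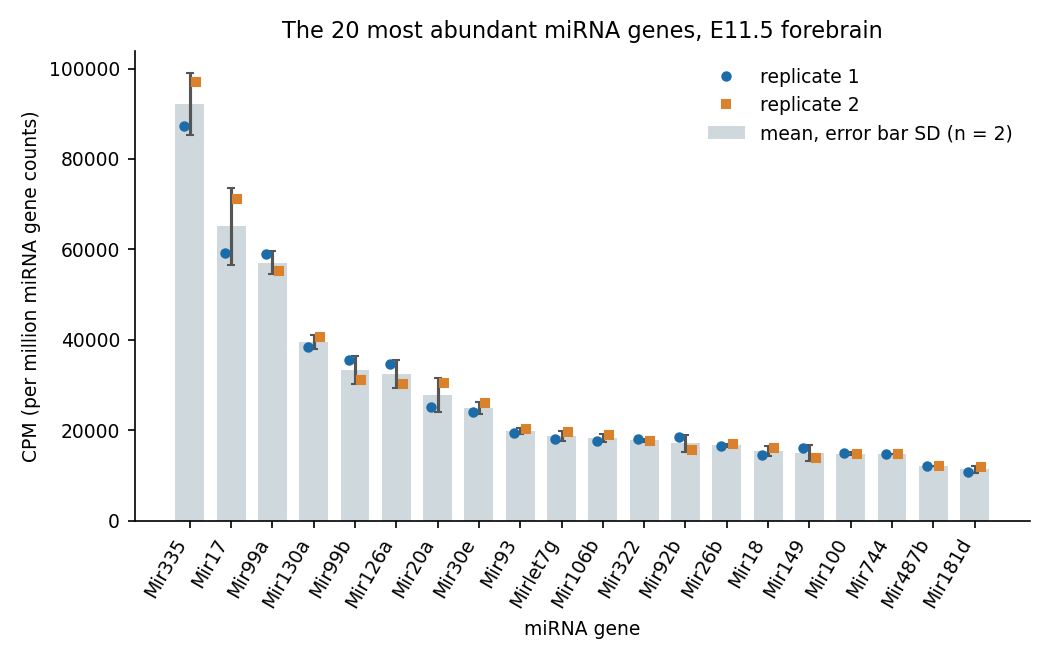
Level of the 20 most abundant miRNA genes (x axis) in CPM (y axis, from 0): bars show the mean, error bars the SD of 2 replicates, and points each replicate library. Mir335 stands at 92176 CPM and Mir181d, the last of the 20, at 11394 CPM.

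The 10 most abundant genes took 41.1% ± 1.49 of the counts and the 20 most abundant 56.4% ± 1.39. For the first 10, the share was 40.0% in replicate 1 (95% Wilson interval 39.96 to 40.1%) and 42.2% in replicate 2 (42.1 to 42.2%). In both libraries, 424 of 1973 miRNA genes had 2 CPM or more, and 466 and 451 genes did so in replicates 1 and 2 alone. A further 1288 genes had no count in either library, which, for genes without near-identical copies, allows a level of up to 2.34 CPM in replicate 1 and 2.31 CPM in replicate 2. Genes with such copies have no such limit and cannot be ranked with certainty, since reads that fit several places are not in the counts. Of the 20 most abundant genes, this applies to Mir487b, whose hairpin shares a stretch of 20 bases with Mir376b. Intervals and these limits cover counting error only, since reads made by PCR are not independent molecules.

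Of the miRNAs known from the developing nervous system or from neurons, 35 of 37 genes with a row had 2 CPM or more in both libraries, and the list took 7.74% ± 0.378 of the counts. Mir92b led it with 17079 ± 1908 CPM, followed by Mir149, in an intron of Gpc1, with 14979 ± 1706 CPM. Mir181d and Mir181c, neighbours in an intron of Nanos3 on chromosome 8, had 11394 ± 758 and 9644 ± 117 CPM. The list's median lay at percentile 99.8 in replicate 1 and 99.9 in replicate 2 of 10000 random lists of the same size, a description of these libraries and not a test. Such high percentiles were not particular to neural miRNAs. Endothelial (99.2 and 99.1), mesenchyme and smooth muscle (98.7 and 98.3), epithelial (98.6 and 98.6) and eye, ear and choroid plexus miRNAs (92.7 and 92.7) also ranked high. Lower were liver, gut and pancreas (77.7 and 77.3), leukocyte (76.2 and 76.5), erythroid (73.0 and 73.8), Hox cluster (43.0 and 38.1) and striated muscle miRNAs (32.1 and 27.3). Low values stood beside the leading neural genes for Mir9 and Mir124a, known from neural progenitors and neurons and named here after their values were seen. Mir9-3 had 479 ± 62.4 CPM and Mir9-2 8.16 ± 3.91 CPM, and the 3 Mir124a genes had 25.6 ± 5.25 CPM together. The hairpins of Mir9 and Mir124a share stretches of 20 bases with their other copies, and reads that fit several places are left out of the gene counts, so the levels of these genes are uncertain.

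The let-7 family, whose maturation LIN28 inhibits in early embryonic tissue, was detected at 2 CPM or more for all 10 genes with a row and took 2.99% ± 0.0777 of the counts. Mirlet7g had 18769.6 ± 1131 CPM, Mirlet7i 6912 ± 328 CPM, Mirlet7d 2504 ± 36.8 CPM and Mir98 1050.4 ± 20.7 CPM. The other members ran from 27.5 ± 1.89 CPM for Mirlet7c-2 to 228 ± 7.26 CPM for Mirlet7f-2, and of these only Mirlet7b, at 134 ± 9.43 CPM, shares no stretch of 20 bases with another hairpin. The list's median lay at percentiles 91.6 and 92.7 of random lists. Mirlet7e and Mirlet7f-1 had no row and were not counted in the list.

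The miR-17-92 cluster and its paralogs took 17.1% ± 1.49 of the counts, and all 15 genes had 2 CPM or more in both libraries. Mir17 and Mir20a, from the same transcript on chromosome 14, were followed in this list by Mir93 and Mir106b, which lie in Mcm7 on chromosome 5 and had 19797.5 ± 634 and 18344 ± 929 CPM. Mir18, the next hairpin after Mir17, had 15364 ± 1125 CPM and Mir92-1 8202 ± 1030.4 CPM. Mir19a and Mir19b-1 of the same transcript, named after their values were seen, had 143 ± 20.6 and 45.8 ± 1.51 CPM. The hairpin of Mir19b-1 shares 20 bases with Mir19b-2 and that of Mir92-1 with Mir92-2, so the levels of both are uncertain. Broadly expressed miRNAs took 16.9% ± 0.1002, with Mir130a, Mir99b, Mir30e and, at 14655 ± 11.5 CPM, Mir744 in the lead, and all 25 genes with a row passed 2 CPM. The order of these lists differed between the libraries, with 16.0% for miR-17-92 and 16.99% for broadly expressed miRNAs in replicate 1 and 18.1% and 16.8% in replicate 2. Both lists had medians above those of every random list in both libraries (percentile 100).

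The imprinted Dlk1-Dio3 cluster of distal chromosome 12, which is transcribed from the maternal copy, took 10.3% ± 0.308 of the counts. Of its 43 genes with a row, 39 had 2 CPM or more in both libraries and 4 had no count. Mir487b had 12059 ± 47.5 CPM, Mir411 11084 ± 1034 CPM, Mir431 10211 ± 1357 CPM and Mir541 9268 ± 694 CPM, and these 4 stand between 109590447 and 109742498 on that chromosome. The hairpin of Mir487b shares a stretch of 20 bases with Mir376b, and that of Mir411 with Mir758. The median of the cluster lay at percentile 100 of random lists in both libraries. The pluripotency clusters, known from embryonic stem cells, took 0.730% ± 0.109 of the counts, and 8 of their 12 genes with a row had 2 CPM or more. Mir302d had 2497 ± 463 CPM, Mir302a 2199 ± 286 CPM, Mir302b 2122 ± 302 CPM and Mir302c 324 ± 39.9 CPM, all on chromosome 3 between 127545228 and 127545689, while the highest level of the other members was 62.8 ± 0.567 CPM for Mir294. This list's median lay at percentiles 75.8 and 76.8.

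The lists of miRNAs known from other cell types or tissues had shares from 3.25% down to 0.0147% of the counts. Which cells of the dissected tissue held these miRNAs was not examined. Mir126a, the single endothelial gene, made up 3.25% ± 0.302, and the mesenchyme and smooth muscle list 2.34% ± 0.174, with Mir143 at 7511 ± 656 CPM, Mir214 at 6296 ± 302 CPM, Mir22 at 4244 ± 405 CPM and Mir140 at 4241 ± 286 CPM. Epithelial miRNAs made up 0.803% ± 0.0382, led by Mir203 at 2553 ± 107 CPM, Mir429 at 1947 ± 287 CPM, Mir205 at 1508 ± 94.98 CPM and Mir200c at 1053 ± 36.9 CPM. Eye, ear and choroid plexus miRNAs made up 0.392% ± 0.00266, with Mir182 at 1567 ± 116 CPM, Mir183 at 1426 ± 46.3 CPM, Mir96 at 540.5 ± 19.3 CPM and Mir204 at 362 ± 74.6 CPM. The leukocyte list, at 0.0796% ± 0.00109, held Mir155 at 400.4 ± 34.2 CPM, Mir223 at 341 ± 31.6 CPM, Mir146 at 36.0 ± 9.00 CPM and Mir150 at 18.2 ± 0.713 CPM. It lacks Mir142, which has no row, and its share became 0.178% when the opposite-strand counts at the places of list members without a row were added, an alternative chosen after the data were seen. The liver, gut and pancreas list, at 0.0640% ± 0.00869, held Mir375 at 248 ± 39.5 CPM, Mir217 at 114 ± 19.1 CPM, Mir194-2 at 95.8 ± 4.70 CPM and Mir192 at 87.3 ± 11.2 CPM. In the erythroid list, at 0.0489% ± 0.0166, Mir451a had 369 ± 176 CPM, Mir144 89.95 ± 2.48 CPM and Mir486 30.2 ± 7.40 CPM.

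Striated muscle miRNAs took 0.0197% ± 0.00840 of the counts, with Mir208b and Mir208a, in introns of the cardiac myosin genes Myh7 and Myh6, at 144 ± 67.1 and 30.3 ± 13.4 CPM, Mir499 at 14.4 ± 0.678 CPM and Mir206 at 5.05 ± 2.79 CPM. Mir1a-1, Mir133a-1, Mir133a-2 and Mir133b, muscle genes named after their values were seen, had no count, and the hairpin of each shares 20 bases with a near copy. The Hox cluster list, from loci used in the hindbrain, spinal cord and trunk, took the smallest share of the 15 lists in the mean, 0.0147% ± 0.00891. Mir10a had 80.9 ± 55.6 CPM, Mir10b 45.9 ± 28.9 CPM, Mir615 10.1 ± 2.28 CPM and Mir196b 6.99 ± 2.26 CPM. The Hox share rested on replicate 1, at 0.0210% against 0.00840% in replicate 2.

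**Figure D2:**
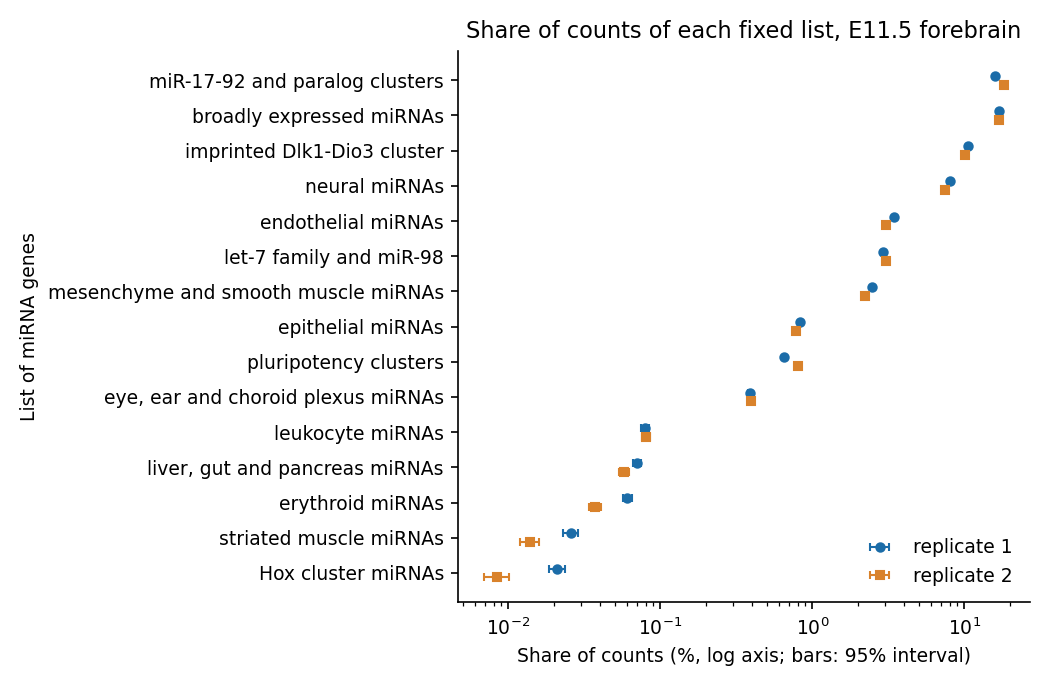
Share of miRNA gene counts in percent (x axis, log scale) for the 15 lists of miRNA genes (y axis): points show each replicate library and bars the 95% Wilson interval of its counts. The mean share runs from 17.1% for the miR-17-92 and paralog clusters to 0.0147% for the Hox cluster miRNAs.

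Summed over members, neural miRNAs exceeded each list of another tissue in both libraries. The log2 ratio was 1.26 ± 0.06 to the endothelial list, 1.72 ± 0.04 to mesenchyme and smooth muscle, 3.27 ± 0.0018 to epithelial miRNAs and 4.30 ± 0.08 to the eye, ear and choroid plexus list. Larger ratios stood against leukocyte (6.60 ± 0.09), liver, gut and pancreas (6.92 ± 0.13), erythroid (7.35 ± 0.43), striated muscle (8.68 ± 0.56) and Hox cluster miRNAs (9.19 ± 0.86). Lists differ in length, and with the median member plus 1 CPM in place of the sum the ratio turned negative for the endothelial list (-7.42), mesenchyme (-1.64), epithelial miRNAs (-2.47) and the eye, ear and choroid plexus list (-1.25). It shrank to 0.00081 for leukocyte, 1.06 for erythroid, 2.00 for liver, gut and pancreas, 4.33 for Hox cluster and 5.41 for striated muscle miRNAs. Many neural members share a stretch of bases with another hairpin, unlike the epithelial and the eye, ear and choroid plexus members. Reads that fit several places are left out of the gene counts, so the neural median can be too low against these lists by an unknown amount. Whether this loss accounts for the reversals against them was not tested. With the opposite-strand counts for members without a row, Mir142 among them, the summed leukocyte ratio was 5.395.

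Between the replicate libraries, Mir10a and Mir10b of the Hox clusters, Mir6236, Mir6240 and Gm26117 were the genes with a mean of 50 counts or more that were furthest apart, all higher in replicate 1. Mir10a (chromosome 11, 96317165 to 96317274) had 120.2 CPM in replicate 1 and 41.6 CPM in replicate 2, a log2 ratio of 1.52 (95% interval 1.07 to 2.01, adjusted p = 1.03e-11 in the exact binomial test). Mir10b, in introns of Hoxd3 and Hoxd4 on chromosome 2, differed by 1.37 (0.79 to 2.01), Mir6236 by 1.67 (1.38 to 1.98), Gm26117 by 1.39 (0.82 to 2.02) and Mir6240 by 1.37 (0.80 to 1.99). Of 398 genes with 10 counts or more in total, 11 differed by 2-fold or more at an adjusted p under 0.05, of which 9 were higher in replicate 1. The other 4 higher genes were Mir451a of erythroid cells with a log2 ratio of 1.01 (0.82 to 1.21), the liver miRNA Mir122 with 1.71 (0.60 to 3.12), Gm23935 with 1.08 (0.77 to 1.40) and Gm24572 with 2.13 (0.68 to 4.28). The genes lower in replicate 1, named outside the fixed rule, were Mir211 at -1.19 (-2.05 to -0.43) and Mir7666 at -1.81 (-3.68 to -0.44). Mir451a fell below 2-fold with TMM scaling (0.95) and with DESeq2 size factors (0.96), and the edgeR exact test at a coefficient of variation of 0.2 called 0 genes, with 13 at an unadjusted p under 0.05.

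Members of the miR-17-92 list were more often lower than higher in replicate 1. Of 15 tested genes, 7 were lower and 2 higher at an adjusted p under 0.05 in the exact binomial test. The counts were 7 and 3 when adjusted over the list alone. This test covers counting error only, without the spread between libraries (a biological coefficient of variation of 10.3% in edgeR). Small shifts of genes with many counts can therefore pass it. Mir17 had a log2 ratio of -0.27 (-0.28 to -0.25) and Mir20a of -0.28 (-0.30 to -0.26), while Mir92-1 stood at 0.26 (0.22 to 0.30). Of the 8 tested pluripotency genes, Mir302a, Mir302b, Mir302c and Mir302d were lower in replicate 1, and 0 were higher (4 and 1 when adjusted over the list alone), with -0.38 (-0.45 to -0.31) for Mir302d. Among 10000 random lists matched on level, the median log2 ratios of these lists, -0.10 and -0.26, lay at percentiles 0.34 and 0.10. The random lists drew each gene separately, whereas Mir17, Mir18, Mir19a and Mir20a share a transcript and Mir302a, Mir302b, Mir302c and Mir302d lie side by side. Such neighbours are not independent, so percentiles of this kind can be too extreme and are not a test. In the Hox list, 2 of 4 tested genes were higher in replicate 1 and 0 lower, with a median of 1.00 at percentile 98.4. In the striated muscle list, Mir208b with 0.99 (0.67 to 1.31) and Mir208a with 0.92 (0.24 to 1.67) were higher among 5 tested genes and 0 were lower, with a median of 0.92 at percentile 99.8. For both lists the counts were the same when adjusted over the list alone.

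The other lists were counted with the same test of counting error alone. Neural miRNAs had 9 genes higher and 1 lower in replicate 1 of 34 tested, and 9 and 1 when adjusted over the list alone. With TMM scaling this became 6 and 4. The Dlk1-Dio3 cluster had 11 higher and 1 lower of 39 (12 and 1 when adjusted over the list alone), but 5 higher and 8 lower with TMM scaling, and its median log2 ratio of 0.07 lay at percentile 39.7 of matched random lists. Mesenchyme and smooth muscle had 6 higher and 1 lower of 9, and 5 and 1 with TMM. Broadly expressed miRNAs had 6 and 4 of 25 (8 and 5 when adjusted over the list alone), and 2 and 7 with TMM. The let-7 list had 1 and 1 of 10, epithelial miRNAs 1 and 1 of 7 (2 and 1 when adjusted over the list alone), eye, ear and choroid plexus 1 and 2 of 5, liver, gut and pancreas 2 and 0 of 7, erythroid 1 and 0 of 3, endothelial 1 and 0 of 1, and leukocyte miRNAs 0 and 0 of 4. With TMM, let-7 had 0 and 1, liver, gut and pancreas 1 and 0 and leukocyte miRNAs 0 and 1, and the other lists of that sentence kept their counts. Except where stated, counts adjusted over the list alone were the same as over all genes. Over all 398 genes, 82 were higher and 31 lower at an adjusted p under 0.05 regardless of size, which became 54 and 52 with TMM and 61 and 49 with DESeq2 size factors.

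**Figure D3:**
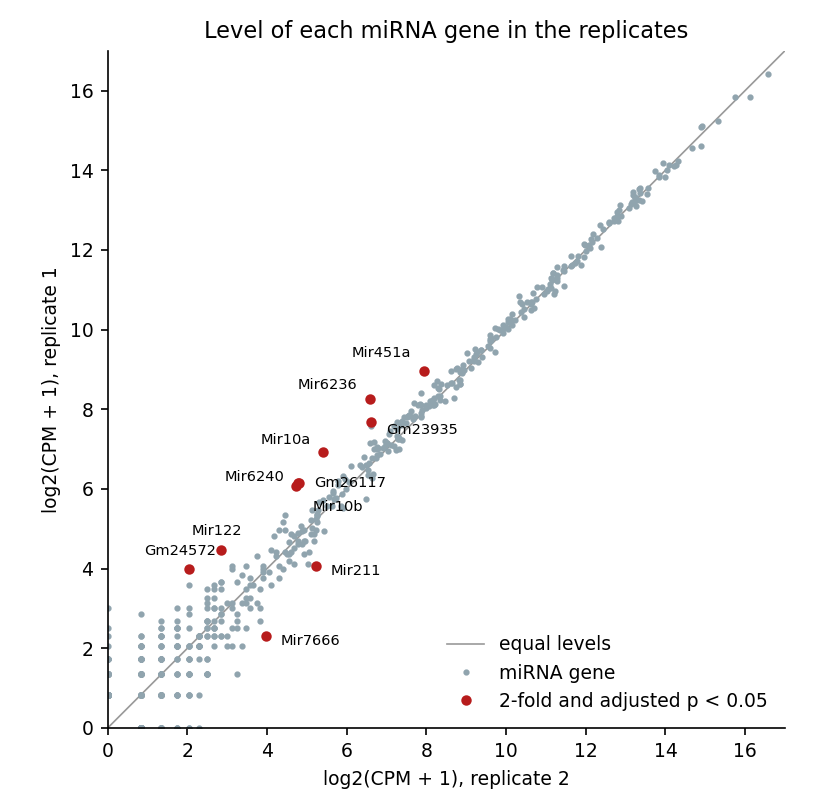
Level of each miRNA gene with a count, as log2(CPM + 1), in replicate 2 (x axis) and replicate 1 (y axis), with the line of equal levels. The 11 genes in red differed by 2-fold or more at an adjusted p under 0.05, and 9 of them lie above the line.

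The libraries agreed across genes with a Pearson r of 0.987 on log2(CPM + 1) and a Spearman rho of 0.936 over 685 genes with a count in either, and genes are not independent replicates. Of 268 genes with 100 counts or more in total, 259 lay within 1.5-fold. The biological coefficient of variation was 10.3% in edgeR. The files were not copies of each other, with a chi-square statistic of 8758 on 397 degrees of freedom over the tested genes. The exact binomial test takes the 2 libraries as they are and compares these libraries, not conditions.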

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

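The counts on the strand opposite to each gene entered the levels and lists only in alternatives (the unstranded column and members without a row), and the values below are those above 3 counts in both libraries, the limit that a count of 0 allows. The tests of this part were all chosen after the counts were seen. As mean counts of the 2 libraries, the opposite strand held 11273 at Gm24321, 8350 at Gm25252, 8194 at Gm25927, 4558 at Mir299b, 4348 at Gm24083, 3489 at Gm25301, 2803 at Gm25750, 1349 at Mir142b, 914 at Mir497b, 127.5 at Gm25641 and 32 at Gm24111. Lower values were 30.5 at Mir203, 21 at Mir3074-1, 19 at Mir374b, 12 at Mir337, 11 at Mir124a-3, 7 at Mir708, 5.50 at Mir126a, 5.50 at Mirlet7b and 5 at Mir219a-1.

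At 12 genes the opposite strand held more counts than the sense strand in both libraries, and these 12 held 99.7% ± 0.0185 (SD, n = 2) of all opposite-strand counts. A strand background of the libraries is argued against, since the opposite strand held 0.00651% of the counts over the 1941 genes that overlap no unlisted miRNA gene. In the M21 annotation, 11 of the 12 overlap a miRNA gene on the other strand that has no row, in order Mir409, Mir376a, Mirlet7e, Mir299a, Mir191, Mir378a, Mir380, Mir142, Mir497, Mir9-1 and Mirlet7f-1, so the counts may be those of these miRNAs, and Mir124a-3 is the exception. All 32 miRNA genes without a row at such places carry identifiers above the highest number among the rows, which would fit genes added to the annotation later. If so, Mir409 at 8751 ± 1890 CPM would rank 34 among the miRNA genes and Mirlet7e at 6357 ± 472 CPM would rank 45, and no biological explanation was tested, since the series has 1 group.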

How the results depend on the processing

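The number of detected genes stayed within 1.5 times of 424 under each alternative limit, scaling and column, from 327 at 10 CPM to 531 at 1 count in both libraries. With the most abundant gene, Mir335, also taken out of the total, the next 10 genes took 37.1% of the remaining counts. The Spearman rho of the replicates moved to 0.991 over genes with 10 counts in total and to 0.990 over genes at 2 CPM, where the many genes near 0 are left out. Of the 11 genes called between the libraries, 10 were shared with TMM and with DESeq2 scaling, 11 without a filter and in the unstranded column, 7 of 7 at a minimum of 100 counts (fewer genes tested), and 0 were called by the edgeR exact test at the larger fixed variation. The coefficient of variation was 0.0100% by the DESeq2 gene-wise median, which is its floor and void as an estimate. Taking Mir335, Mir17 and Mir99a out of the total, which by construction raises lists without them, gave 9.85% for neural miRNAs, 3.81% for let-7, 13.4% for miR-17-92, 0.930% for pluripotency, 13.1% for Dlk1-Dio3, 0.101% for leukocyte, 4.13% for endothelial, 2.98% for mesenchyme, 1.02% for epithelial, 0.4995% for eye, ear and choroid plexus, 0.0814% for liver, gut and pancreas and 21.5% for broadly expressed miRNAs, which then exceeded miR-17-92. In the unstranded column, whose total is larger, shares were 2.89% for let-7, 9.95% for Dlk1-Dio3, 0.0769% for leukocyte, 0.379% for eye, ear and choroid plexus and 16.3% for broadly expressed miRNAs, and the epithelial log2 ratio was 3.27. With the opposite-strand counts of members without a row, chosen after seeing the data, let-7 had 3.50%, Dlk1-Dio3 11.97%, leukocyte 0.178% (from Mir142) and eye, ear and choroid plexus 0.379%, broadly expressed miRNAs (16.9%) exceeded miR-17-92 (16.5%), and the log2 ratio of neural miRNAs was 5.395 to leukocyte and 3.27 to epithelial miRNAs. With list medians, that ratio reversed to -7.42 for endothelial, -1.64 for mesenchyme, -2.47 for epithelial and -1.25 for eye, ear and choroid plexus, and moved to 1.06 for erythroid, 0.00081 for leukocyte, 5.41 for striated muscle, 2.00 for liver, gut and pancreas and 4.33 for Hox; the cause was not tested. Without the top member of each list it was 8.97 for erythroid, 7.25 for leukocyte, 1.92 for mesenchyme, 3.46 for epithelial, 4.68 for eye, ear and choroid plexus, 10.2 for striated muscle and 7.27 for liver, gut and pancreas, and could not be computed for the single endothelial gene. Levels of the 65 named genes changed by at most 1.19% with TMM and 3.52% in the unstranded column. With 2 replicates, a value from either library alone lies within 1 SD of the mean by construction, so leaving out a replicate tests nothing here. No paired analysis was possible because the series holds 1 group. Depth limits genes under 10 counts, which were not tested.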

Other observations

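Imprinted loci, put together after the levels were seen, gave 21.7% ± 0.159 (SD, n = 2) of the miRNA gene counts from 48 genes. Reads that fit several places, 40.4% of the mapped reads, are not in this total, so the share among all miRNA reads is unknown. The Dlk1-Dio3 cluster contributed 10.3% ± 0.308 and Mir335 of Mest 9.22% ± 0.681. At the Gnas locus on chromosome 2, Mir298 had 11238 ± 1064 CPM and Mir296 9999 ± 965 CPM, together 2.12% ± 0.203. At the Igf2 and H19 loci on chromosome 7, Mir483, in an intron of the growth factor gene Igf2, had 597 ± 114 CPM and Mir675, in an exon of H19, 29.1 ± 0.811 CPM. The 48 genes held 21.6% of the counts in replicate 1 and 21.8% in replicate 2, while Mir335 was lower and the Gnas genes higher in replicate 1.

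Some related genes were put together after the levels were seen. Mir99a, Mir99b and Mir100, which belong to the miR-99 family, made up 10.5% ± 0.595 of the counts. Mir130a, Mir130b, Mir301 and Mir301b, which share a seed sequence, made up 5.35% ± 0.256, and Mir130b had 10237 ± 938 CPM against 283 ± 10.1 CPM for its neighbour Mir301b on chromosome 16. On the X chromosome, 5 genes of the cluster around Mir322 made up 2.08% ± 0.0872, of which Mir322 had 17764 ± 328 CPM, Mir351 1553 ± 401 CPM, Mir503 666 ± 95.4 CPM, Mir542 588 ± 11.3 CPM and Mir450b 222 ± 36.5 CPM.

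The tests of the following patterns were all chosen after the values were seen. Mir9, Mir124a and let-7a, miRNAs with several near-identical copies, had few counts. List members that share 20 bases with another hairpin had a median of 106 CPM over 64 genes, against 671 CPM over the 132 others, a difference of -2.66 in median log2(CPM + 1) (p = 0.00013, permutation test), but the 64 include the miRNAs that drew attention to the pattern and copies that are not independent. With those families left out and the copies of a family summed, 26 families that share a stretch had a median of 516 CPM and 127 others 601 CPM, a difference of -0.24 (p = 0.844, permutation test of families). Summing copies can lift families that share a stretch against single genes, so this comparison cannot decide the question. Reads that fit several places are left out of all gene counts, and how many came from Mir9, Mir124a and let-7a is unknown. Their loss stays open as a cause. It cannot be told apart from low levels in the tissue, since the multimapping reads are not split by gene. The rows of Mir9, Mir124a and let-7a add up to 654.8 CPM. No biological explanation was tested.

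Mir10a and Mir10b of the Hox list, Mir208a and Mir208b of the striated muscle list and Mir451a were higher in replicate 1, while Mir615, Mir196b, Mir499, Mir206 and Mir1b of these lists did not pass the test. TMM moves every log2 ratio by the same amount, and took the median of all 398 tested genes from 0.065 to -0.0018. Library scaling is argued against by the small size of this shift, which left the 9 tested Hox and muscle genes at a median log2 ratio of 0.86, with 8 of them above 0. These lists were picked for their high ratios, so the median that remains is not independent support for a difference. Mir144, an erythroid gene next to Mir451a, did not rise with it, and differed by -0.056 (-0.44 to 0.33) against 1.01 (0.82 to 1.21) for Mir451a. Mir486, the remaining erythroid gene with a row, differed by -0.50 (-1.20 to 0.18). The upper limit for Mir144 lies below the lower limit for Mir451a, and Mir486 did not rise either. These values argue against more red blood cells in replicate 1 as the cause for Mir451a. This holds only if these miRNAs follow the number of red blood cells alike, which was not examined. A larger amount of tissue from outside the forebrain in replicate 1 may account for part of the pattern and stays open: the median log2 ratio lay at percentile 90.6 of matched random lists for liver, gut and pancreas miRNAs, of which Mir122 was higher by 1.71 (0.60 to 3.12), and at 95.9 for mesenchyme and smooth muscle miRNAs, of which 6 of 9 were higher (5 with TMM), but at 45.0 for epithelial, 23.3 for erythroid, 14.9 for leukocyte and 8.21 for eye, ear and choroid plexus miRNAs. The neural list, which stands for the forebrain itself, lay at percentile 87.2, so a high percentile was not limited to lists of other tissues. The replicates are pools of different embryos, and no other biological explanation was tested.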
